A study of Gallus gallus with 5 samples.

How the data were processed

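The study measured messenger RNA by bulk MARS-seq, a 3'-end RNA sequencing method in which oligo-dT primed cDNA carries a sample barcode and a unique molecular identifier (UMI), so that copies of the same molecule made by amplification are counted once. The 5 libraries analysed were made from PO/AH tissue of Cobb broiler chicks at day 3 after hatching, 6 h after a mimic of gga-miR-210a-3p was injected into that tissue. A mimic is a synthetic double-stranded RNA that acts as the mature microRNA. All 5 belong to a single group and are named here by the numbers in their titles (1, 2, 6, 9 and 10). The labels do not say that each library came from a separate animal, so the spread between libraries may be partly or wholly technical.

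Per the series design text, the authors trimmed reads with cutadapt, aligned them with STAR to the 3' ends of genes of the galGal5 chicken assembly, removed duplicates by gene and UMI, counted with HTSeq and corrected the UMI counts for saturation. Tool versions are not given in the sources used here. Per the file headers, the authors deposited raw counts and normalised counts for each gene. The raw counts are whole numbers. The normalised values, a signal on the scale of counts, were made by the authors by dividing each library's counts by 1 size factor per library. Those factors, recovered from the deposited values, were 0.818 for library 1, 0.873 for library 2, 0.890 for library 6, 1.08 for library 9 and 1.33 for library 10. DESeq2's median-of-ratios factors computed on these 5 libraries alone were larger, with deposited factors at 0.967 to 0.977 times them, so the deposited factors were not those of these 5 libraries and this set of genes taken alone. The authors also deposited the limits for their own comparison: adjusted p at most 0.05, absolute log2 fold change at least 0.58 (1.5-fold) and a largest count of at least 30. 0 columns of per-sample values lay outside the 5 libraries, and rows naming no gene held 0% of counts.

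Genes carry versioned Ensembl IDs, 11476 of 11476, while the series text names RefSeq annotation. The table's name column repeats the ID (0 IDs differ), and 0 of the IDs occur in the RefSeq gene table used for names (assembly GRCg7b). No gene is therefore named by symbol, no coordinates are given, and pathway or cell type lists fixed in advance were not used. Naive chicks, named in the design text as the reference group, were not analysed here, nor was the authors' table of fold changes.

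Levels are CPM, each gene's count divided by the total of its library in units of 1e+06 counts. The spread between libraries was fitted with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr and an intercept-only design, giving a common and a tagwise biological coefficient of variation (BCV), the relative SD between libraries left after counting error. The filter required its minimum level in each of the 5 libraries. A gene low in any library was left out whatever its mean, and 7503 genes were kept. Correlations and distances between libraries used log2(CPM + 0.5) of these genes. The common BCV of a pair of libraries was fitted on the genes that passed the filter in that pair, so the genes differ between pairs. The BCV steps were tested on simulated counts for the 11476 genes with the real means and totals. With a BCV of 0.18 for every gene the common BCV came out at 0.179. With 200 genes set to 0.6 and the rest at 0.18, the common BCV came out at 0.205, so a set of highly variable genes raises it above the value of most genes. The 8 genes ranked most variable were all (100%) from those 200. The median tagwise BCV over all 200 was 0.315, because edgeR pulls gene values towards the trend, and 1.5% of them came out over 0.5. Tagwise values of variable genes taken as a set were therefore low estimates in the simulation. Whether this holds for the few genes ranked highest, which are picked on the estimate itself, was not examined. The same pull raises the values of genes that vary less than the trend. All genes outside the 200 were set to 0.18, unlike real genes, so the size of the pull may differ in the real data. Of the 200 genes ranked most variable, 84% were among those set to 0.6. With edgeR's robust option the median tagwise BCV of the genes set to 0.6 was 0.516.

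The rule set in advance for naming genes took the 8 genes with the highest mean CPM. It also took the 8 with the largest tagwise BCV among fitted genes of at least 20 CPM. As the IDs have no symbols, the first 2 of each set are given with their values and the rest are summarised. Alternatives set before the data were examined were TMM and DESeq2 1.42.0 size factors, no low-count filter, DESeq2 dispersions and leaving out each library. Deposited size factors, thinning to equal totals and robust shrinkage were chosen after seeing the data. Total counts per library ranged from 3446463 to 5445181. A gene with no count in a library could lie at up to 3 counts, which is 0.551 CPM in the deepest library and 0.870 CPM in the shallowest. These limits cover counting error only.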

Results

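Gene expression was profiled in PO/AH tissue, the usual abbreviation for the preoptic area and anterior hypothalamus, a brain region that takes part in the control of body temperature. The tissue came from 3-day-old broiler chicks 6 h after injection of a mimic of gga-miR-210a-3p, the mature 3' arm of a microRNA. The series concerns heat conditioning of fathers and thermal resilience of their offspring, and the purpose of this part, per its design text, was to compare mimic-injected with naive chicks. The naive libraries were not analysed here, so the values below describe the mimic-injected group and give no effect of the mimic. The group held 5 libraries with a mean of 4215140 ± 795310 UMI counts (SD, n = 5). Library 1 was the shallowest at 3446463 counts, followed by library 2 at 3764534, library 6 at 3875774, library 9 at 4543759 and library 10 at 5445181.

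Transcripts of 11476 genes were listed, of which 10 had no count in any of the 5 libraries. Between 11174 and 11348 genes had at least 1 count in a given library. A few transcripts made up much of the mRNA. The 172 genes at 1000 CPM or more, 1.5% of the genes, held 44.7% of the counts, and the 1482 genes between 100 and 1000 CPM held a further 37.1%. At the other end, the 1611 genes under 1 CPM held 0.0977% of the counts. The 10 highest genes of each library took 14.9% ± 0.706 of its counts (SD, n = 5), and 4735 genes reached a mean of 20 CPM.

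The most abundant transcript was ENSGALG00000035334.1, at 37682 ± 3937 CPM (SD, n = 5), and the next was ENSGALG00000041091.1, at 28833 ± 1508 CPM. Levels of ENSGALG00000035334.1 ranged from 33326 CPM in library 1 to 42889 CPM in library 6, a 1.29-fold range. ENSGALG00000041091.1 varied less, 1.14-fold, from 26690 CPM in library 10 to 30454 CPM in library 6. The 8 most abundant genes had mean levels from 7052 to 37682 CPM, tagwise BCVs from 0.12 to 0.18 and ranges between the highest and lowest library of 1.14-fold to 1.77-fold. Each of these ranges rests on at least 25363 counts per library, so counting error adds little to it. Any error from the saturation correction was not assessed.

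Most genes differed modestly between libraries that had received the same injection. The common BCV was 0.184, and the median tagwise BCV of the 7503 fitted genes was 0.175, with the central 90% of genes between 0.128 and 0.289. These tagwise values include edgeR's pull towards the trend, which narrows their range and raises the values of steady genes. ENSGALG00000041091.1 had a tagwise BCV of 0.122, with an SD of 1508 CPM around its mean of 28833 CPM. Genes at 1000 CPM or more had the lowest median. The median tagwise BCV was 0.133 for genes at 1000 CPM or more, 0.141 between 100 and 1000 CPM, 0.170 between 20 and 100 CPM and 0.208 between 5 and 20 CPM. It was 0.189 for the 368 genes of 1 to 5 CPM that passed the low-count filter. Genes at this level pass only if they are low in no library, which selects for a narrow range, so 0.189 does not describe the class. Counting error alone gave a median CV of 1.23% at 1000 CPM or more, 3.6% between 100 and 1000 CPM, 7.42% between 20 and 100 CPM and 15.2% between 5 and 20 CPM. Genes of 1 to 5 CPM were poorly resolved at this depth, with a median counting CV of 32.6% over all 2670 of them.

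**Figure D1:**
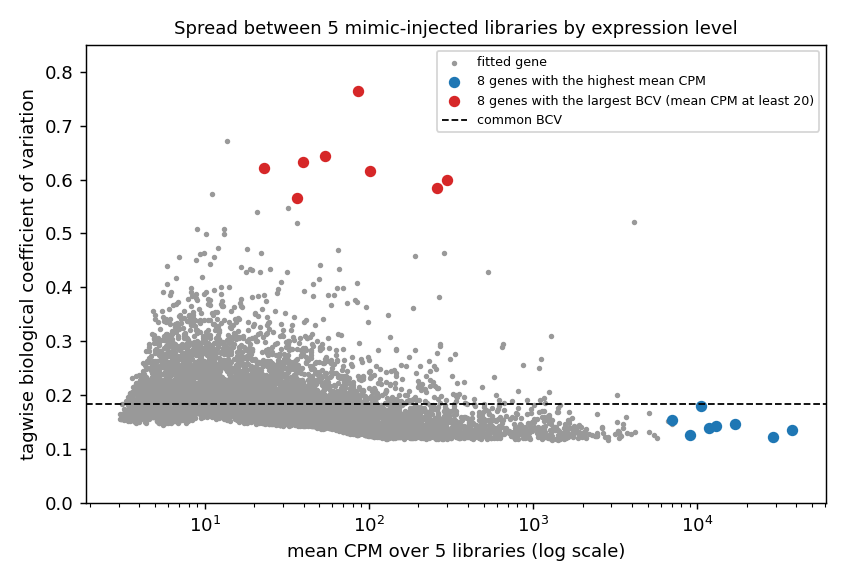
Tagwise biological coefficient of variation (vertical axis, no unit) of each of the 7503 fitted genes against its mean CPM over the 5 mimic-injected libraries (horizontal axis, log scale), with the common BCV of 0.184 as a dashed line. The 8 most abundant genes (blue) lie between 0.12 and 0.18, below the dashed line, and the 8 most variable genes of at least 20 CPM (red) lie between 0.565 and 0.764.

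Some genes varied far more. Among fitted genes of at least 20 CPM, 96 had a tagwise BCV over 0.3 and 12 had one over 0.5. The filter left out genes low in any library, so some strongly variable genes could not enter. Of the 3081 genes of 20 to 100 CPM, 3079 were fitted. In the simulation, only 1.5% of the genes set to a BCV of 0.6 came out over 0.5. All other simulated genes shared a single BCV, unlike real genes, so this rate cannot be carried over to the real count. Whether the real count over 0.5 is a low estimate was not tested. The limit of 0.3 was not examined in the simulation, and neither count gives the number of highly variable genes. The most variable fitted gene, ENSGALG00000031631.1, had a BCV of 0.764 and a mean of 86.2 ± 73.5 CPM (SD, n = 5). It stood at 145 CPM in library 1, 160.0 CPM in library 9 and 109 CPM in library 10, but at 9.30 CPM in library 2 and 7.48 CPM in library 6, a 21.4-fold range with 29 counts in the lowest library. The next, ENSGALG00000032453.1, had a BCV of 0.644 and a mean of 53.9 ± 52.0 CPM. It reached 117 CPM in library 1 and 105 CPM in library 10, against 13.8 CPM in library 2, 19.9 CPM in library 6 and 14.5 CPM in library 9, an 8.44-fold range. The other genes of the 8 most variable had mean levels down to 22.9 CPM and up to 300.1 CPM, and the ranges of all 8 ran from 8.14-fold to 21.4-fold. The number of genes over a BCV of 0.5, over all levels, was 16 with 5 libraries and 9 without library 1. It was 27 with edgeR's robust shrinkage, 47 with DESeq2 dispersions and 229 with no filter on low counts.

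**Figure D2:**
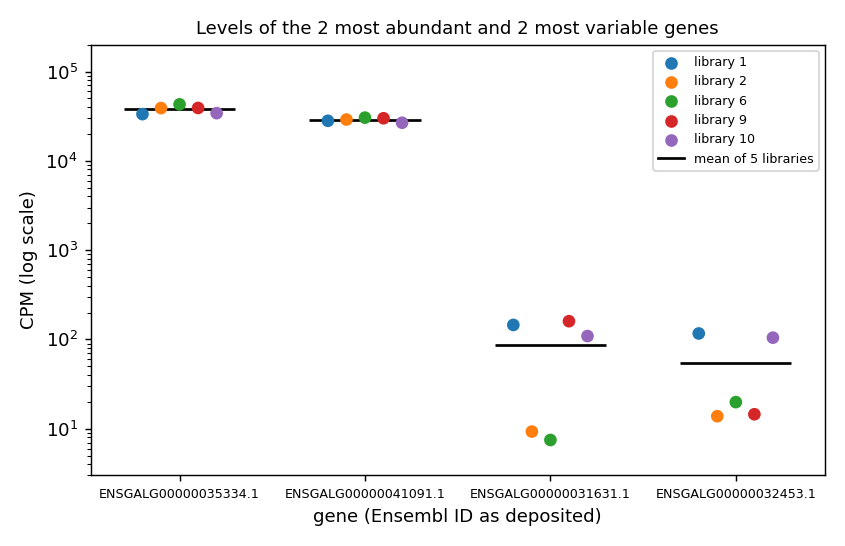
CPM (vertical axis, log scale) of the 2 most abundant and the 2 most variable genes in each of the 5 mimic-injected libraries (coloured points), with the mean of the 5 libraries as a black line. The points of the abundant genes lie within 1.29-fold of each other, and those of the variable genes spread over 8.44-fold and 21.4-fold.

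Across genes, which are not independent replicates, log2 levels of any pair of libraries had a Pearson r between 0.966 and 0.982. The share of genes that differed by more than 2-fold between a pair of libraries ran from 1.85% for libraries 9 and 10 to 6.08% for libraries 1 and 6. The mean chi-square per gene for a difference between the counts of a pair lay between 8.50 and 19.7 over the 10 pairs. No pair held counts alike enough to be merged, and n was kept at 5, which does not show that the libraries came from separate animals. Library 1 was the least similar to the others, with a mean r to the other libraries of 0.969, against 0.976 for each of libraries 2, 6, 9 and 10. Pairs with library 1 had a common BCV of 0.207 ± 0.0183 (SD over 4 pairs), and the 6 remaining pairs had 0.165 ± 0.0169. Pairs share libraries and are not independent, so no test was made of this difference.

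**Figure D3:**
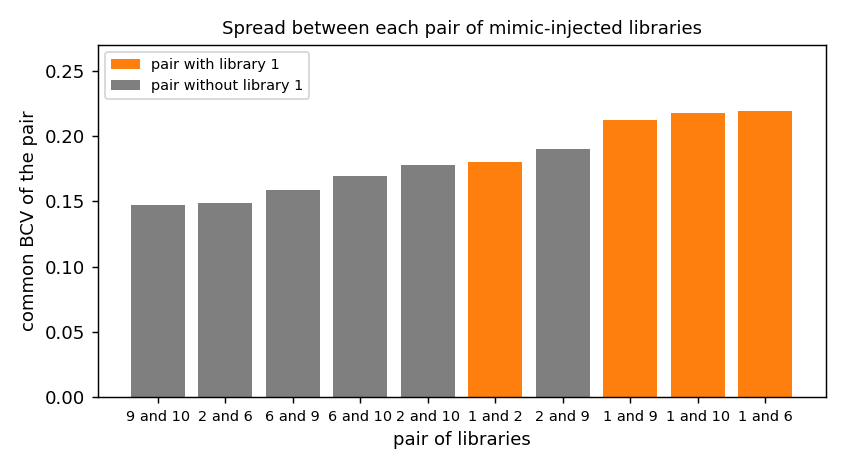
Common biological coefficient of variation (vertical axis, no unit) of each of the 10 pairs of mimic-injected libraries (horizontal axis), ordered by value. The 4 pairs with library 1 (orange) lie between 0.18 and 0.219, and the 6 pairs without it (grey) between 0.147 and 0.190.

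The authors' deposited table of limits requires a largest count of at least 30 before a gene can be called changed between mimic-injected and naive chicks. In the mimic-injected libraries alone, 7303 of the 11476 genes (63.6%) met that minimum. The 1.5-fold limit in the same table is 0.58 on the log2 scale. The median SD of log2 levels between the 5 libraries was 0.14 for genes at 1000 CPM or more, 0.17 for genes of 100 to 1000 CPM, 0.23 for genes of 20 to 100 CPM, 0.34 for genes of 5 to 20 CPM, 0.47 for genes of 1 to 5 CPM and 0.52 for genes under 1 CPM. These SDs are between single libraries and include counting error, so they are not the error of a difference between group means. They were taken on log2(CPM + 0.5) over all genes of a class, and the offset narrows them at low levels.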

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

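The tests of depth and scaling in this part were set out before their results were seen, but the pattern they address was found in these data. Of 23 measures examined for a library far from the other 4, 2 stood out by Dixon's gap test. Chance alone marks about 5% of groups of independent values.

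Library 1 had a mean correlation to the other libraries of 0.969, against 0.976 for the rest, and its gap took up 0.944 of the whole range (limit 0.71). These means share pairs of libraries and are not independent, so the limit and the 5% rate do not strictly apply to them. On the first principal component, the axis of largest variance (37.9%), the gap of library 1 was 0.533, under the limit. Scores on this axis were -27.7 for library 1, -6.39 for library 2, 10.1 for library 6, 11.7 for library 9 and 12.2 for library 10. That is also the order of their total counts and of their title numbers. Among 7195 genes of at least 5 CPM, 357 (4.96%) had a single library apart from the other 4, close to the 5.45% in simulated counts with no library apart. Library 1 was that library for 39.2% of them, where an even share is 20%, with 57 genes at which it was highest and 83 at which it was lowest. A lower number of counts is argued against as the whole cause, since 35.5% remained after thinning every library to the smallest total. Thinning evens out the counts only, so other properties that go with depth or with the order of the libraries were not tested. An effect of a few abundant genes is argued against by 40.7% after leaving out the 100 highest genes, and scaling by total count by 41.2% with TMM factors. The TMM factors ran from 0.991 to 1.02, with 0.996 for library 1, so the check with them had little room to change the share. RNA quality, dissection and a true difference between animals stay open and were not tested, because the gene IDs carry no names to test markers with, and genes that vary together can give a single library this share by chance.

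The third most abundant gene, ENSGALG00000032142.1, stood at 21345 CPM in library 9 against 15238 to 16341 CPM in the other 4, a gap of 0.793 of its range on the log2 scale.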

How the results depend on the processing

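The number of genes at 20 CPM or more, 4735, ran from 4686 to 4761 when single libraries were left out, and the common BCV of 0.184 from 0.166 to 0.189. The median tagwise BCV ran from 0.163 to 0.184 without single libraries, and rose from 0.175 to 0.209 with no filter on low counts. That setting adds genes of low count and also better-counted genes that were low in any library. ENSGALG00000002244.5, at 0.516 CPM in library 6 and 24.4 CPM in library 9, was left out by the filter. The number of genes with a tagwise BCV over 0.5, 16, was the least stable result: 229 with no filter, 47 with DESeq2 dispersions, 27 with robust shrinkage (chosen after seeing the data) and 9 to 17 without single libraries, 9 being without library 1. The robust option by construction pulls outlying genes less to the trend, and raised the BCV of ENSGALG00000031631.1 from 0.764 to 1.06. DESeq2 gave 1.14, and the cause of its difference was not tested. Leaving out single libraries moved the mean of ENSGALG00000031631.1 (86.2 CPM) between 67.8 and 105.9 CPM and that of ENSGALG00000032453.1 (53.9 CPM) between 38.2 CPM, without library 1, and 63.9 CPM. Thinning to equal totals gave a common BCV of 0.183. The 3 planned results on the contrast with naive chicks (genes past the authors' limits, gene list tests, miR-210 seed matches) were not run, since fold changes, naive libraries, gene symbols and 3' UTR sequences were not used here. No paired analysis was possible because a single group was analysed. Depth limits genes under 5 CPM: the median counting CV was 32.6% between 1 and 5 CPM and 62.0% under 1 CPM, and the spread between libraries was fitted for 368 of 2670 genes in the first class and for 0 of 1611 in the second.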

Other observations

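The test in this part was chosen after the values were seen. Of the 8 most variable genes, 4 were highest in library 6 and lowest in libraries 1 and 2, and these genes were picked out after their values were seen. ENSGALG00000023622.3 stood at 774 CPM in library 6, 357 CPM in library 9 and 211 CPM in library 10, against 84.1 CPM in library 1 and 75.2 CPM in library 2. ENSGALG00000043064.1 followed the same order at the top, with 646 CPM in library 6, 275 CPM in library 9 and 244 CPM in library 10, against 60.1 CPM in library 1 and 76.8 CPM in library 2. Of the 172 genes at 1000 CPM or more, 1 had a BCV over 0.5. This was ENSGALG00000032456.1, the gene with rank 16 by mean level, likewise chosen after its values were seen. It had a BCV of 0.522 and stood at 10299 CPM in library 1, 4299 CPM in library 10, 2996 CPM in library 2, 1679 CPM in library 9 and 1322 CPM in library 6, a 7.79-fold range with at least 5123 counts in each library. With 5 libraries no correlation was computed.

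A few genes were near 0 in some libraries and clearly counted in others. ENSGALG00000040901.1 had 105 counts in library 6, 1 count in library 1 and 0 counts in libraries 2, 9 and 10. One hypothesis is that animals of both sexes were used, in which case genes of the female-specific W chromosome could switch on and off together. Over all 30 divisions of the 5 libraries into on (at least 30 counts in each) and off (at most 3 counts in each), at most 1 gene followed the same division. No set of genes switching together was therefore seen, but the hypothesis cannot be told apart from its opposite, since the table may hold few W-linked genes and animals of a single sex would give the same result.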
